A study of Homo sapiens with 7 samples.

How the data were processed

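RUNX2 and H3K27ac chromatin immunoprecipitation followed by sequencing was done in the T-ALL cell lines KARPAS-45 and PER-117, with 1 library per line and antibody. Per the labels' protocols, KARPAS-45 grew with 20% and PER-117 with 10% fetal bovine serum, chromatin was crosslinked for 10 min with 1.1% formaldehyde, sheared to 200 to 300 bp and precipitated with 10 ug of antibody. The 3 input libraries have no peak list and were not analysed here. The submitters' processing notes name STAR 2.4.2a, MACS2 and the build hg38. Their roles, parameters and thresholds, and the input used for each list, are not given in the sources used here. Each list was taken as deposited, 1 per ChIP library. The authors deposited 10 columns per peak in the narrowPeak layout: a display score, which matched 10 times the −log10 q without its decimals, a fold enrichment (a linear ratio), −log10 p and −log10 q. The deposited RUNX2 lists also give a summit per line, while column 10 of the H3K27ac lists is 100 throughout and was not used as a summit. The deposited −log10 q reached down to 0.431 and 1.01 in the H3K27ac lists of KARPAS-45 and PER-117 and to 1.31 and 1.30 in the RUNX2 lists. Read counts and depth were not analysed here. A longer list may come from depth, antibody performance or thresholds as well as from the cells, so peak numbers were not read as amounts of binding.

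Several summits of 1 RUNX2 peak were joined to 1 interval with the summit of highest fold enrichment, and together with setting apart 127 and 40 lines on other sequences this reduced 46275 lines to 42911 intervals in KARPAS-45 and 23043 to 21027 in PER-117. Chromosomes 1 to 22 and X were used, and calls on the mitochondrial genome and on unplaced contigs were counted apart. Genes came from a RefSeq table of GRCh38.p14, whose 59084 entries on these chromosomes include 19974 protein-coding genes. It gives gene spans without strand or exons, so windows at transcription start sites were replaced by windows at either end of the span, and exons and introns were not resolved. No genome sequence was used here, so the planned motif analysis and matching on GC content were not run.

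Intervals were called overlapping at 1 bp or more, a summit acetylated when inside an H3K27ac region, and a RUNX2 peak specific to a line when no peak of the other line overlapped it. Expected shares came from 100 random placements of each list within its chromosomes, and again within 100 kb of each peak. The chromosome end was taken as the last annotated or called position. Shares have Wilson 95% intervals. The 15 gene lists, with 226 genes, covered RUNX and CBFB, immature and progenitor, KMT2A-fusion target, T-lineage, T-ALL transcription factor, migration, mitochondrial, glycolysis, survival, bone, B-cell, myeloid, erythroid, NK and non-blood genes. The count of members with RUNX2 at a gene end was placed among 10000 random lists of protein-coding genes of the same size, matched on gene-end acetylation in that line and also unmatched. H3K27ac regions were joined within 12.5 kb into domains ranked by covered bases, and the 300 broadest were kept. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap and interval code was run on simulated data, where the gap between planted and counted overlaps was 0. Both counts used the same function and decoys near a peak were left out, so this gap was fixed by construction. The share from random placement had a relative error of up to 12.3%, and Wilson intervals covered the true share in 94.5% of draws.

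The gene lists, the main settings and the rule for naming genes were fixed before the data were examined. The rule named RUNX1, RUNX2, RUNX3 and CBFB, the gene with the nearest end to the 10 strongest peaks, the 10 best ranked shared peaks and the 10 strongest line-specific peaks of each line, from each list up to 4 members bound in both lines (strongest first, by the lower of their fold enrichments) and up to 3 per line with either mark in that line only in alphabetical order, and genes with an end in the 5 broadest domains of each line. Further list members were named to complete a small count, after their values were seen, and in the longest gene clusters of a domain only some genes are named. Genes of chromosome 8 were not named, by the same rule, and some genes the rule names are not reported here. Distances are to the nearest end of a protein-coding gene. Alternatives fixed beforehand were a −log10 q of 10 or more, the 5000 strongest RUNX2 peaks with the 10000 strongest H3K27ac regions, a window of 2.5 kb, midpoints for summits, overlap of 50% of the shorter interval or summits within 100 bp, the wider 50% of H3K27ac regions, merging of regions within 1 kb, a margin of 500 bp around H3K27ac, a margin of 1 kb for line-specific peaks, and other domain settings. Alternatives added after the data were seen were H3K27ac regions with −log10 q of 2 or more, H3K27ac lists of equal covered length (by q or by width), the whole gene span, and the local random placement. The −log10 q of the KARPAS-45 H3K27ac regions, as deposited, resembled that of the preceding region of the list. It was only weakly related to region width and to the PER-117 values. No H3K27ac fold enrichment is reported, and settings that rank H3K27ac regions by q may select KARPAS-45 regions nearly irrespective of their strength.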

Results

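RUNX2, a Runt-domain transcription factor best known as the master regulator of bone formation, was mapped by chromatin immunoprecipitation and sequencing in 2 T-cell acute lymphoblastic leukemia (T-ALL) cell lines, KARPAS-45 and PER-117. H3K27ac, the histone mark of active promoters and enhancers, was mapped in the same lines. KARPAS-45 is a line with a KMT2A rearrangement. The study concerned RUNX2 dependency in immature and KMT2A-rearranged T-ALL, and the comparisons below ask where RUNX2 bound, how far binding was shared, and which bound sites were acetylated. There was 1 library per cell line and antibody, so there were no replicates, no test between the lines was possible, and each difference is one between libraries. Of the 7 samples, 3 were inputs and 4 had a peak list. On chromosomes 1 to 22 and X, the RUNX2 lists held 42911 peaks in KARPAS-45 and 21027 in PER-117. The H3K27ac lists held 63265 regions covering 167 Mb in KARPAS-45 and 53263 regions covering 76.2 Mb in PER-117. Read depth was not given in the files, so a site missing from a list was not called at an unknown depth. Fold enrichments are the authors' values for single peaks and rank peaks within a list only. Intervals in brackets are Wilson 95% intervals and cover counting error only. The gene table carries no strand, so a gene was called bound or acetylated at a gene end when a peak lay within 1 kb of either end of its span. Bound and acetylated have this sense for the gene lists below.

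Of the 3 RUNX genes and CBFB, 4 carried a RUNX2 peak at a gene end in KARPAS-45 and 3 in PER-117. Random lists matched on gene-end acetylation had medians of 3 and 2, which put the list at percentiles 83.5 and 73.5. In KARPAS-45 all 4 were bound, so no higher percentile was possible. With 4 genes these percentiles cannot tell whether the group differed from acetylated genes in general. RUNX3, a T-cell differentiation factor, had a gene-end peak with a fold enrichment of 27.4 in KARPAS-45 and 32.8 in PER-117. RUNX1, a regulator of blood stem cells that is often mutated in leukemia, had 19.7 and 17.1, and RUNX2 itself had 20.0 and 7.08. CBFB, the shared partner subunit of the RUNX proteins, was bound at a gene end in KARPAS-45 with 5.58, while in PER-117 its peaks lay inside the gene, the strongest with 9.10. All 4 genes were acetylated at a gene end in both lines. With the KARPAS-45 H3K27ac list shortened to the covered length of the PER-117 list, 3 were in KARPAS-45 by width and 0 by q. Peaks were spread along the bodies of these genes: RUNX1 (chromosome 21, 34787801 to 35049302, hg38) held 29 RUNX2 peaks in KARPAS-45 and 14 in PER-117, and RUNX2 (chromosome 6, 45328330 to 45551082) held 17 and 11. SUPT3H, which overlaps the lower end of the RUNX2 span and encodes a subunit of a transcription coactivator complex, held 35 peaks in KARPAS-45 and 5 in PER-117.

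**Figure D1:**
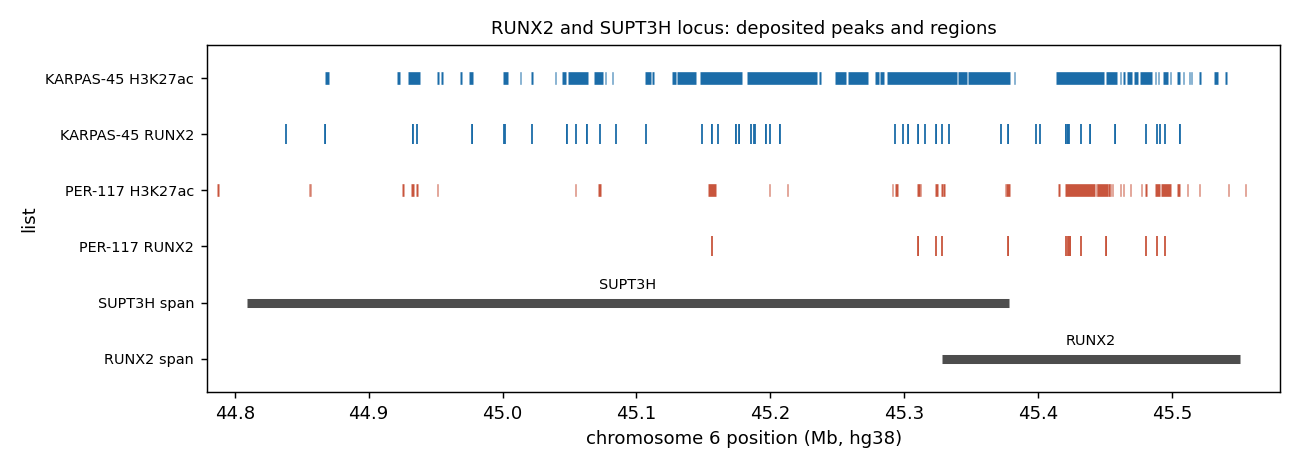
Map of the RUNX2 and SUPT3H locus on chromosome 6 (x axis, position in Mb, hg38), with 1 track per peak list and the spans of both genes. Bars are deposited H3K27ac regions to scale and ticks mark RUNX2 peaks, which number 48 in KARPAS-45 and 14 in PER-117 within the window, where H3K27ac covers 362 kb in KARPAS-45 and 89.8 kb in PER-117.

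Of the 10 strongest RUNX2 peaks of each line, 9 in KARPAS-45 and 10 in PER-117 are named here by the nearest protein-coding gene end, and all of these overlapped a peak of the other line. In KARPAS-45 the highest fold enrichment, 96.5, lay 144 bp from the end of LOC105375012 (chromosome 6, 30463327 to 30464096). It was followed by 93.9 inside FNDC3B (chromosome 3, 172106945 to 172107842), 82.9 at 2349 bp from ZNF541 and 80.1 at 4111 bp from FBP2, a gluconeogenic enzyme. A peak of 79.6 lay inside IGF2R, the receptor that clears insulin-like growth factor 2, a peak of 76.8 at 212 bp from PROSER3 and another of 76.8 inside MSI2, an RNA-binding protein of blood stem cells. The remaining named sites were 73.3 within PUDP, 63079 bp from STS, and 73.2 in FCRLB, 334 bp from its end. In PER-117 the strongest peak, with 63.7, lay inside SMCO1 (chromosome 3, 196511854 to 196512431). Next came 59.8 at 3467 bp from NFE2, an erythroid and megakaryocyte factor, 57.1 at GSPT1, a translation termination factor, and 51.7 at PSIP1, the chromatin tether of KMT2A complexes. CD84, a lymphocyte receptor, had 49.1, ZNF541 48.9, DAD1 47.7 at a distance of 8348 bp, SDE2 46.6, and both CFLAR, an inhibitor of death receptor signalling, and OTUD5 45.8. The sites near LOC105375012, ZNF541, FBP2, IGF2R and FCRLB lay outside H3K27ac in both lines, as did the site in OTUD5, whereas those at PROSER3, MSI2, SMCO1, NFE2, GSPT1, PSIP1, CD84, DAD1, SDE2 and CFLAR were acetylated in both. The sites in FNDC3B and near STS were acetylated in KARPAS-45 only.

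By location, 23.4% of the 42911 KARPAS-45 summits (23.03 to 23.8) and 29.2% of the 21027 PER-117 summits (28.6 to 29.8) lay within 1 kb of the end of a protein-coding gene. Random placement within chromosomes gave means of 2.72% and 2.86%, and placement within 100 kb of each peak gave 4.98% and 5.57%. Further summits lay inside protein-coding genes away from their ends, 44.4% in KARPAS-45 and 40.7% in PER-117, and outside all annotated genes, 23.1% and 21.1%. Local random placement gave 54.9% and 54.5% for gene interiors and 29.6% and 29.3% for the space outside genes. Of 19974 protein-coding genes, 9653 (48.3%) carried RUNX2 at a gene end in KARPAS-45 and 6494 (32.5%) in PER-117. Among the 10359 genes acetylated at a gene end in both lines, RUNX2 was present at 81.4% in KARPAS-45 and 59.1% in PER-117. It was present at 4.73% and 1.30% of the 7056 genes acetylated in neither.

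Between the lines, the best ranked shared peaks included those with the nearest gene end at ZNF541, PSIP1, DAD1, CRTC3, NOC3L, SSH3, TRAP1 and GTF2A2. The peak named for NOC3L lay 15259 bp from it, inside PLCE1. CRTC3, a CREB coactivator, had a peak 16128 bp from its end with a fold enrichment of 64.8 in KARPAS-45 and 38.2 in PER-117. Outside chromosome 8, the strongest peaks without a partner in PER-117 lay in or near HSDL1 (60.8), CFAP46 (57.3), LOC101929773 (56.4), RBMX2 (55.2), ZNF584 (55.1), WDR27 (54.8), ACSF3 (54.4), IQCH (54.4) and LOC124904579 (53.5). The peaks named for LOC101929773 and LOC124904579 lay 18298 and 25547 bp from them. Those found in PER-117 and not in KARPAS-45 had their nearest gene end at PATZ1 (36.1), a zinc finger factor of thymocyte development, RPN1 (35.1), PRSS57 (34.6), LOC124904584 (32.9), LOC107983989 (32.9), MMP2 (32.3), CENPU (32.3), XYLT1 (31.9) and SLC37A1 (31.0). The peak named for MMP2 lay 43276 bp from it. Those named for LOC124904584 and CENPU lay 29952 and 9129 bp from them, inside PIK3C2B and PRIMPOL. PRSS57 is a neutrophil granule protease, and its peak lay 84 bp from the gene end.

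Of the KARPAS-45 RUNX2 peaks, 13387 (31.2%, 30.8 to 31.6) overlapped a PER-117 peak by 1 bp or more, and 13383 PER-117 peaks (63.6%, 63.0 to 64.3) overlapped a KARPAS-45 peak. Random placement within 100 kb gave means of 1.41% and 2.84%. Gene-end peaks were shared more often than distal ones, 48.0% against 26.1% in KARPAS-45 and 79.3% against 57.2% in PER-117. Sharing rose with the fold enrichment, from 16.2% in the weakest 10% of the KARPAS-45 list to 66.5% in the strongest, and from 45.2% to 79.9% in PER-117. With the 5000 strongest peaks of each list the share was 38% in each line.

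**Figure D2:**
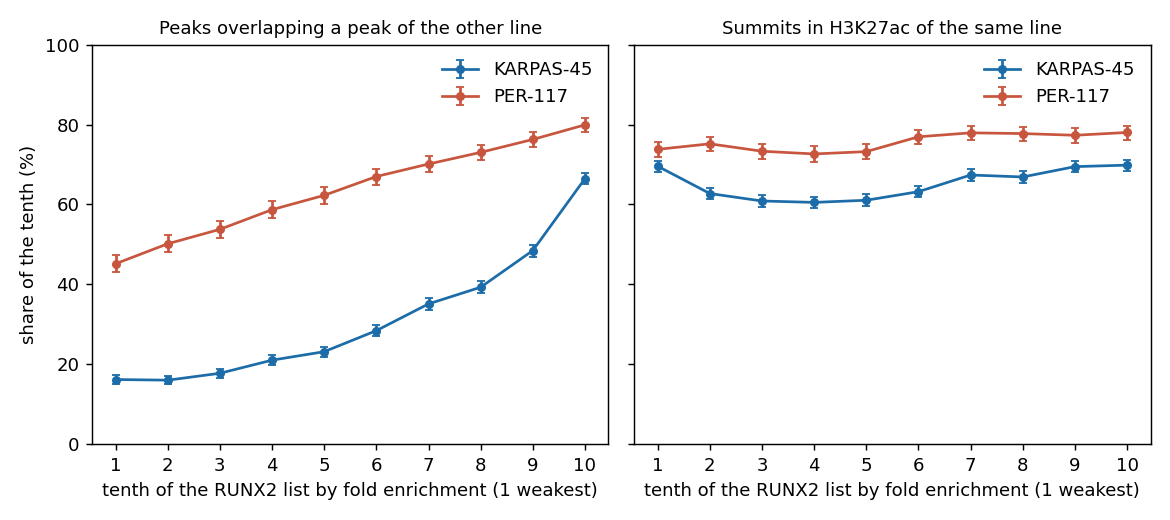
Share of RUNX2 peaks (y axis, percent) in each 10% of a list ordered by fold enrichment (x axis, 1 weakest, 10 strongest), with Wilson 95% intervals as bars. The left panel shows overlap with a peak of the other line, which rises from 16.2% to 66.5% in KARPAS-45 and from 45.2% to 79.9% in PER-117, and the right panel shows summits inside H3K27ac of the same line, between 60.5% and 69.8% in KARPAS-45 and between 72.6% and 78.0% in PER-117.

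With the full lists, RUNX2 summits lay in acetylated chromatin more often than random positions did, and the share depended on the length of the lists. In KARPAS-45, 27958 summits (65.2%, 64.7 to 65.6) fell inside an H3K27ac region of the same line, and in PER-117 15899 did (75.6%, 75.0 to 76.2). Local random placement gave 19.0% and 9.79%. At gene ends 91.8% and 92.4% of the summits were acetylated, and away from them 57.0% and 68.7%. The KARPAS-45 share was 25.6% when that list was limited to its widest regions, up to the covered length of the PER-117 list. With the 5000 strongest RUNX2 peaks and 10000 strongest H3K27ac regions of each line, the shares were 9.06% and 49.3%. This setting ranks H3K27ac regions by q, which may say little of their strength in KARPAS-45. The 9.06% is therefore not read as low acetylation of strong sites.

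With the full lists, RUNX2 sites found in a single line differed from shared sites mainly in the acetylation of the other line. Peaks shared by the lines were acetylated in KARPAS-45 and in PER-117 alike, 77.4% and 75.9% of the 13387 shared KARPAS-45 peaks. The 13383 shared PER-117 peaks were acetylated at 76.3% in PER-117 and 77.7% in KARPAS-45. The 29524 peaks found in KARPAS-45 only were acetylated at 59.6% (59.0 to 60.2) in KARPAS-45 and at 26.9% (26.4 to 27.4) in PER-117. On the same peaks, 10199 were acetylated in KARPAS-45 alone, 545 in PER-117 alone and 7395 in both. The 7644 peaks found in PER-117 only were acetylated at 74.4% (73.4 to 75.3) in PER-117 and at 35.9% (34.8 to 37.0) in KARPAS-45. Of these, 3188 were acetylated in PER-117 alone and 247 in KARPAS-45 alone. Away from gene ends, KARPAS-45-only peaks stood at 53.4% in KARPAS-45 and 18.4% in PER-117, and shared ones at 67.1% and 66.5%. Distal PER-117-only peaks stood at 71.3% in PER-117 and 28.4% in KARPAS-45, and shared ones at 66.7% and 67.3%. Of the named sites found in a single line, those near CFAP46, LOC124904579 and LOC107983989 were acetylated in neither line and that near LOC124904584 in both, and the others, such as HSDL1 and PATZ1, only in the line with the RUNX2 peak. Equal covered length, widest regions first, shortens only the KARPAS-45 H3K27ac list, to 5379 regions. The KARPAS-45-only peaks were then acetylated at 23.7% in KARPAS-45 and 26.9% in PER-117, so the difference within these peaks did not keep its direction. The PER-117-only peaks were then acetylated at 12.8% in KARPAS-45, and at 15.8% with the list shortened by q. In the PER-117 H3K27ac list alone, which does not depend on that choice, the KARPAS-45-only peaks stood at 26.9% and the shared peaks at 75.9%. Shared peaks overlap a PER-117 RUNX2 peak by definition, and 75.6% of all PER-117 summits lay in that list. This contrast therefore restates in large part the overlap of both marks within PER-117.

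**Figure D3:**
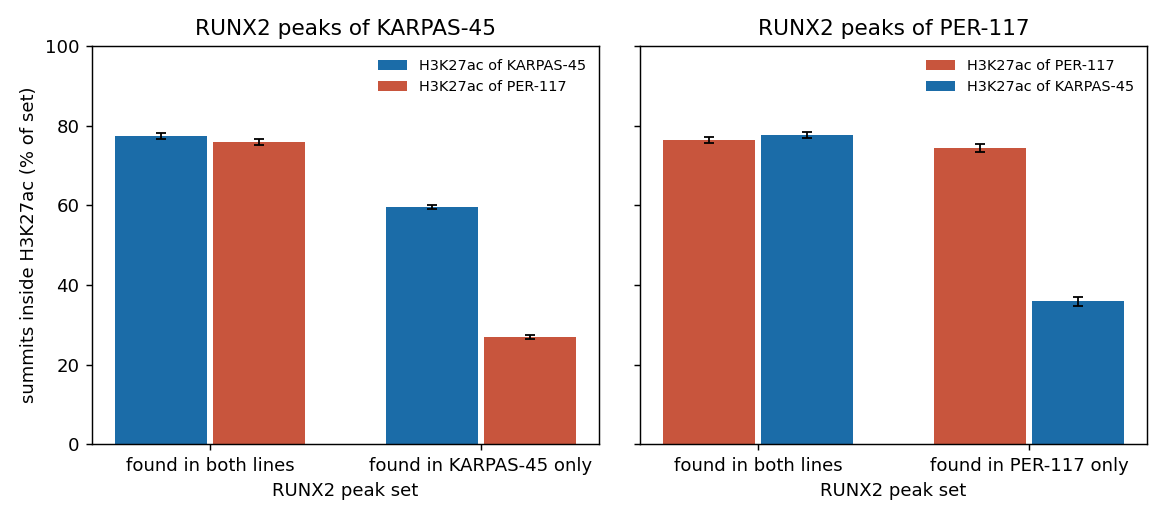
Share of RUNX2 summits inside H3K27ac regions (y axis, percent of the set) for peaks found in both lines and in a single line (x axis), for the KARPAS-45 list (left) and the PER-117 list (right). Bars are coloured by the line whose H3K27ac regions were used and black lines are Wilson 95% intervals, with 59.6% against 26.9% for peaks found in KARPAS-45 only and 74.4% against 35.9% for peaks found in PER-117 only.

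H3K27ac regions themselves were shared at 35.3% in KARPAS-45 (35.0 to 35.7) and 58.2% in PER-117 (57.8 to 58.6), with local random means of 16.2% and 26.7%. Regions at gene ends were shared at 75.9% and 86.5%, distal regions at 25.6% and 50.6%. A RUNX2 peak of the same line was present in 59.6% of the shared KARPAS-45 regions and in 15.8% of those found in KARPAS-45 only, and in 33.5% and 14.7% of the PER-117 regions. These shares were not matched on region width, and a wider region can both overlap another and hold a peak by its length alone. Of protein-coding genes, 12193 (61.0%) were acetylated at a gene end in KARPAS-45 and 11084 (55.5%) in PER-117. At equal covered length, widest regions first, 76.2% of 5379 KARPAS-45 regions and 20.9% of 53263 PER-117 regions were shared, so neither order of the lines is free of the make-up of the lists. In the KARPAS-45 list the −log10 q of a region resembled that of the preceding region (Spearman rho 0.774 across regions, against 0.0366 in PER-117). Settings that rank KARPAS-45 regions by q were run, but are not read as ranking them by strength.

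Of 28 T-lineage genes, 22 carried RUNX2 at a gene end in KARPAS-45 and 15 in PER-117, and those 15 were bound in both. CD3E, a chain of the T-cell receptor complex, had fold enrichments of 41.6 in KARPAS-45 and 23.5 in PER-117. The adhesion receptor CD2 had 34.2 and 16.6, CD1A, a marker of cortical thymocytes, 44.2 and 12.4, and the costimulatory receptor CD28 17.8 and 10.4. All 28 genes were acetylated in KARPAS-45 and 21 in PER-117, and the 7 acetylated at a gene end in KARPAS-45 alone were the coreceptors CD4, CD8A and CD8B, the T-cell markers CD5 and CD1A, the T-cell factor GATA3 and the NOTCH target DTX1. Inside the genes, DTX1, GATA3, CD4 and CD8B held H3K27ac in PER-117 as well. CD247, CD3G and NOTCH1 carried gene-end RUNX2 in KARPAS-45 only, while inside the genes PER-117 had 5, 0 and 4 RUNX2 peaks. Matched on gene-end acetylation, the list stood at percentile 63.0 of 10000 random lists in KARPAS-45 and 89.6 in PER-117. These percentiles, here and below, describe the libraries. Without matching they were 99.95 and 98.8. The order of the lines in acetylation held in the following settings, which apply to both lists. With only the wider regions of each list, 27 genes were acetylated in KARPAS-45 and 18 in PER-117. A window of 2.5 kb gave 28 and 22, regions of −log10 q of 2 or more 24 and 20, and the whole gene span 28 and 25. The order turned at equal covered length, widest first. That setting shortens only the KARPAS-45 list and can only lower its count, so it cannot decide the order. There, 17 genes were acetylated in both lines, 3 in KARPAS-45 alone (CD8A, CD8B and CD1A) and 4 in PER-117 alone. Over all 15 lists, 120 of 226 genes carried gene-end RUNX2 in KARPAS-45 and 87 in PER-117, which turned to 33 and 39 with the 5000 strongest peaks of each line. Gene-end H3K27ac was present at 142 and 139, and at 79 in KARPAS-45 at equal covered length, widest first. List members beyond the rule fixed beforehand, such as CD4 and GATA3, were named after their values were seen.

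Immature and progenitor-associated genes were bound at 7 of 18 gene ends in KARPAS-45 and 3 in PER-117, with matched percentiles of 25.7 and 31.8, and at 11 and 7 with a window of 2.5 kb. LYL1, a basic helix-loop-helix factor of early T-ALL, had a gene-end peak of 57.2 in KARPAS-45 and 16.6 in PER-117, FLT3, a progenitor receptor kinase, 31.2 and 5.16, and ZEB2, a repressor linked to immature T-ALL, 5.2 and 4.72. The myeloid factor CEBPA, the receptor kinases KIT and IGF1R and the homeobox gene MEIS1 carried gene-end RUNX2 in KARPAS-45 only. Inside KIT and IGF1R, PER-117 had 1 and 8 RUNX2 peaks, and 0 in CEBPA and MEIS1. At gene ends, BCL11A, CD34, CEBPA, KIT, MEIS1 and MN1 were acetylated in KARPAS-45 only, the myeloid and stem cell factors SPI1 and GATA2 in PER-117 only, and HHEX, LMO2, MEF2C, ERG, HOXA9 and HOXA10 in neither. Inside the genes, CD34 held 4 H3K27ac regions in each line, SPI1 held 1 in KARPAS-45, and ERG held 20 regions (39.1 kb) and 5 RUNX2 peaks in PER-117 against 1 region and 1 peak in KARPAS-45. The KMT2A-fusion targets were bound at 12 of 20 genes in KARPAS-45 and 9 in PER-117, with matched percentiles of 85.2 and 86.5, and at 5 and 4 with RUNX2 peaks of −log10 q of 10 or more. JMJD1C, a demethylase-family protein, had 8.69 and 5.87, and SUPT3H 9.33 and 5.39. BCL2, CDK6 and MEIS1 were bound at a gene end in KARPAS-45 only, while BCL2 and CDK6 each held 6 RUNX2 peaks inside the gene in PER-117. HOXA5, HOXA7, HOXA9 and HOXA10, the homeobox genes commonly activated by KMT2A fusions, held no RUNX2 peak and no H3K27ac region in either line. Of 16 T-ALL transcription factors, 9 were bound in KARPAS-45 and 5 in PER-117, among them TCF3 (22.6 and 7.29) and TCF12 (11.97 and 12.8), both E-proteins. LDB1, LMO1, MYB and TLX1 were bound at a gene end in KARPAS-45 only, and TAL1, TAL2, TLX3 and LMO2 had neither mark at a gene end. Inside LDB1 there was 1 RUNX2 peak in PER-117. The matched percentiles were 89.4 and 71.8, and gene-end H3K27ac was present at 9 of the 16 genes in KARPAS-45 and 7 in PER-117. The KARPAS-45 count was 7 with regions of −log10 q of 2 or more and at equal covered length by width, and 2 by q. Each of these settings drops regions and can only lower a count, and equal length drops KARPAS-45 regions alone. The loss of the excess therefore does not decide whether it came from the length of the list. At equal covered length, widest first, BCL11A, CD34 and MEIS1 were still acetylated at a gene end in KARPAS-45 only, while CEBPA, KIT and MN1 were acetylated in neither line.

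**Figure D4:**
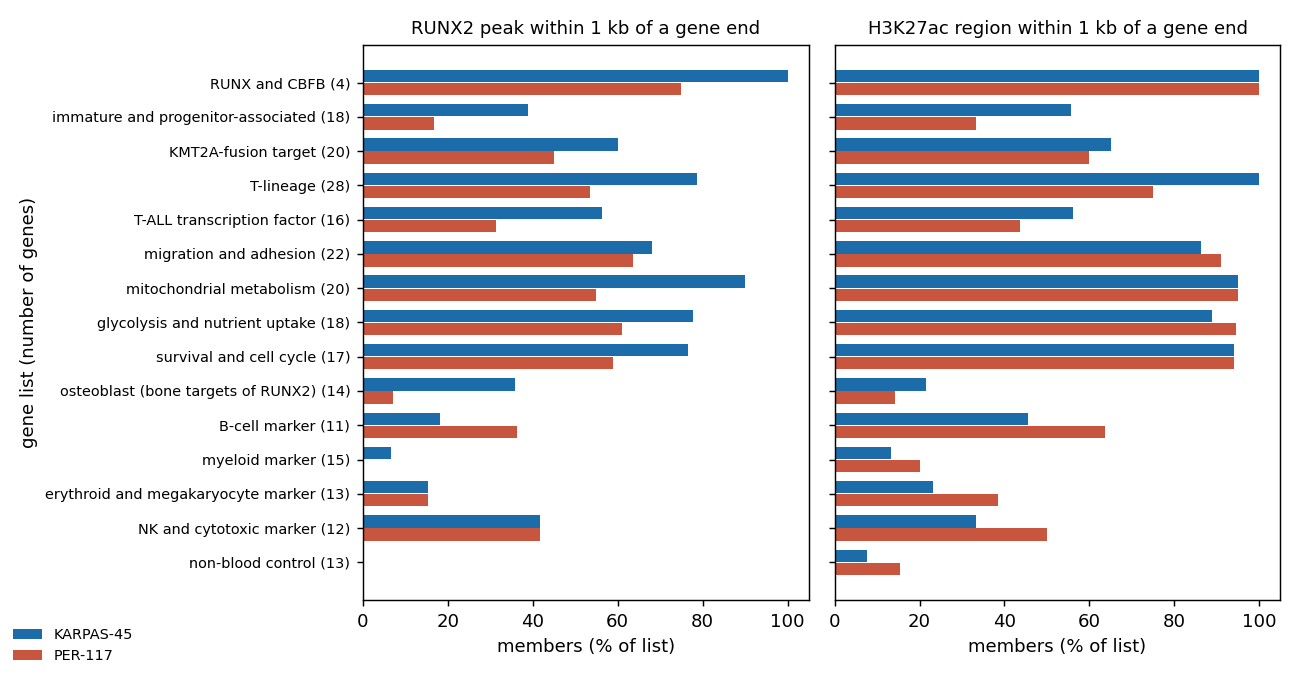
Share of the genes of each fixed list (y axis, number of genes in brackets) with a RUNX2 peak (left) or an H3K27ac region (right) within 1 kb of a gene end (x axis, percent of the list), in KARPAS-45 (blue) and PER-117 (red). T-lineage genes reach 28 of 28 acetylated in KARPAS-45 and 21 in PER-117, and the non-blood control list has 0 of 13 genes with RUNX2 in either line.

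Migration and adhesion genes were bound at 15 of 22 gene ends in KARPAS-45 and 14 in PER-117. RAC2, a small GTPase of blood cells, had fold enrichments of 16.9 and 24.5, the integrin chain ITGA4 14.7 and 13.0, ITGAL 15.9 and 12.2 and the adhesion molecule ICAM2 17.1 and 12.1. At gene ends, the gut-homing receptor CCR9 and ITGA5 were bound in KARPAS-45 only and the skin-homing receptor CCR4 and RHOH in PER-117 only, while inside RHOH there were 6 RUNX2 peaks in each line and inside CCR9 and ITGA5 1 each in PER-117. The matched percentiles were 57.1 and 86.8. CD44 was acetylated in PER-117 only. Mitochondrial genes were bound at 18 of 20 gene ends in KARPAS-45 and 11 in PER-117, while 19 were acetylated in each line. At equal covered length, 10 by width or 6 by q were acetylated in KARPAS-45. TFAM, which maintains mitochondrial DNA, had 43.2 and 27.2, the ATP synthase subunit ATP5F1B 22.4 and 19.5, CPT1A, of fatty acid import, 13.1 and 12.8, and SDHA, of complex II, 10.4 and 11.3. COX4I1, COX5A and IDH2 were bound in KARPAS-45 only. The matched percentiles were 97.7 and 51.4. Glycolysis and nutrient uptake genes were bound at 14 of 18 and 11 of 18, including PGK1 (37.1 and 11.5), GAPDH (13.3 and 10.9), the glutamine carrier SLC1A5 (16.1 and 9.99) and the glucose carrier SLC2A1 (11.7 and 6.81). SLC16A3, SLC2A3 and SLC7A5 were bound in KARPAS-45 only. Survival and cell cycle genes were bound at 13 of 17 and 10 of 17, with the kinase PIM1 at 15.5 and 10.1, the cyclin CCND3 at 7.75 and 33.6 and CDKN2A at 5.61 and 11.5. CCND2 carried both marks in PER-117 and neither in KARPAS-45, whereas BCL2, BCL2L11 and CDK6 were bound at a gene end in KARPAS-45 only. Inside BCL2, BCL2L11 and CDK6, PER-117 had 6, 1 and 6 RUNX2 peaks. Matched percentiles were 83.8 and 71.8 for glycolysis and 66.6 and 65.5 for survival genes. With the 5000 strongest peaks the mitochondrial counts were 3 and 6 and the survival counts 1 and 5, which turns the order of the lines.

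Bone targets of RUNX2 were bound at 5 of 14 gene ends in KARPAS-45 and 1 in PER-117: the collagen gene COL1A1 in both (19.2 and 4.18), and SP7, SPP1, PHEX and DMP1 in KARPAS-45 only. Of these, SPP1 and DMP1 had no H3K27ac in either line. The matched percentiles were 96.85 and 35.9, and 17.96 and 1.89 without matching. B-cell markers were bound at 2 of 11 and 4 of 11, with the surrogate light chain gene IGLL1 at 3.40 and 18.6, CD79B in KARPAS-45 only and CD22, CR2 and VPREB1 in PER-117 only. Myeloid markers were bound at 1 of 15 and 0 of 15, the former ITGAX, and CD33 and CEBPE were acetylated in PER-117 only. Erythroid and megakaryocyte markers were bound at 2 of 13 in each line, GP1BA in both (17.2 and 14.4), SLC4A1 in KARPAS-45 and ITGA2B in PER-117. At gene ends, GATA1, HBA1 and ITGA2B were acetylated in PER-117 only, and inside ITGA2B there was 1 H3K27ac region and 1 RUNX2 peak in each line. NK and cytotoxic markers were bound at 5 of 12 in each line, among them the pore-forming protein PRF1 (11.5 and 12.4), NKG7 (6.02 and 16.5), EOMES (5.16 and 4.82) and TBX21, with GNLY in KARPAS-45 only and FCGR3A in PER-117 only. None of 13 non-blood control genes was bound at a gene end in either line, while 2 in each line were with a window of 2.5 kb. Matched percentiles were 4.03 and 47.7 for B-cell, 12.6 and 2.95 for myeloid, 23.5 and 20.97 for erythroid and megakaryocyte, 91.4 and 86.3 for NK and 6.09 and 7.19 for non-blood genes. With RUNX2 peaks of −log10 q of 10 or more, the NK counts were 1 and 3, the bone counts 3 and 0 and the B-cell counts 0 and 3.

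Broad acetylated domains were made by joining neighbouring H3K27ac regions. The broadest in KARPAS-45 spanned 691 kb at PTPRC (chromosome 1, 198553116 to 199244096), the CD45 phosphatase of leukocytes, with 60 RUNX2 peaks. It was followed by 555 kb at LOC124901483 on chromosome 6 with 58 peaks, 607 kb on chromosome 1 that holds the T-cell kinase LCK and the deacetylase HDAC1 with 51 peaks, and 456 kb at LDLRAD4 and FAM210A on chromosome 18 with 42 peaks. In PER-117 the broadest spanned 331 kb at CIITA, DEXI, CLEC16A and SOCS1 (chromosome 16, 10933587 to 11264396), with 21 peaks. CIITA is the MHC class II transactivator and SOCS1 a brake on cytokine signalling. Next came 253 kb at LIF and OSM on chromosome 22, 309.6 kb at ZMIZ1, a cofactor of NOTCH1, 225 kb at SEPTIN9 and 231 kb at IQSEC1, with 8, 13, 18 and 11 peaks. All 300 broadest domains of each line held a RUNX2 peak of that line, against means of 62.1% and 35.5% for domains of the same lengths placed at random. The domains had medians of 127 and 40.1 kb of H3K27ac and 16 and 7 RUNX2 peaks, and random domains were not matched on acetylation. The contrast therefore sets broad domains no further apart than the general overlap of both marks. Of the 300, 85 in KARPAS-45 (28.3%) and 96 in PER-117 (32.0%) overlapped a domain among the 300 of the other line, including those at PTPRC, LCK, ZMIZ1 and SEPTIN9.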

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

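All results in this part are calls outside the chromosomes compared, and no explanation of them was tested. The KARPAS-45 RUNX2 list held 31 calls on the mitochondrial genome, with a highest fold enrichment of 1.92, and the PER-117 list held 3, with a highest of 1.79. On contigs not placed on a chromosome there were 59 RUNX2 and 114 H3K27ac calls in KARPAS-45, and 37 RUNX2 and 53 H3K27ac calls in PER-117. In KARPAS-45 these do not make up all of the 127 RUNX2 and 168 H3K27ac lines set apart. The sequences of the rest are not reported here.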

How the results depend on the processing

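The settings named as later in this paragraph were chosen after seeing the data, the others beforehand. No paired analysis was possible because each cell line and antibody had 1 library. Values are percents, KARPAS-45 before PER-117 unless stated. With the 5000 strongest RUNX2 peaks and 10000 strongest H3K27ac regions, gene-end summits were 18.9 and 22.5, shared RUNX2 peaks 38 and 38, RUNX2 in H3K27ac 9.06 and 49.3, KARPAS-45-only peaks 8.06 in KARPAS-45 and 13.3 in PER-117 H3K27ac, PER-117-only peaks 50.6 in PER-117 and 6.62 in KARPAS-45 H3K27ac, and list genes with RUNX2 33 and 39 in number. RUNX2 peaks with −log10 q of 10 or more gave 29.6 and 63.0 shared, 68.8 and 78.4 in H3K27ac, 65.0 and 32.9 for KARPAS-45-only peaks in the own and the other H3K27ac, 80.5 and 38.1 for PER-117-only peaks, 27.4 for PER-117 gene-end summits and 98.7 for PER-117 domains with RUNX2. A window of 2.5 kb gave 29.9 and 36.5 at gene ends. Overlap of 50% of the shorter interval gave 29.9 and 61.1 for shared RUNX2 peaks and 34.1 and 55.8 for shared H3K27ac regions, and summits within 100 bp gave 25.2 and 51.4. The wider 50% of H3K27ac regions gave 42.9 and 62.1 shared, 58.2 and 71.5 of RUNX2 summits acetylated, 52.3 and 23.5 for KARPAS-45-only and 70.2 and 31.4 for PER-117-only peaks (own, other). Merging regions within 1 kb gave 36.5 and 61.0 shared, and a margin of 500 bp gave 71.2 and 82.9 acetylated. With no other peak within 1 kb, KARPAS-45-only peaks stood at 57.1 and 22.6 and PER-117-only peaks at 71.3 and 26.2 (own, other). The 1000 broadest domains gave 98.6 in PER-117. Of the later settings, H3K27ac with −log10 q of 2 or more gave 32.2 and 53.6 shared, 54.2 and 74.0 acetylated, 49.2 and 24.97 for KARPAS-45-only and 72.4 and 29.4 for PER-117-only peaks (own, other). Equal covered length by q gave 37.3 and 25.4 shared, 29.2 of KARPAS-45 summits acetylated, 26.9 for KARPAS-45-only peaks in KARPAS-45, 15.8 for PER-117-only peaks in KARPAS-45 and 73 list genes acetylated in KARPAS-45. Equal length, widest first, gave 76.2 and 20.9, 25.6, 23.7, 12.8 and 79 in that order. Both equal-length settings shorten only the KARPAS-45 list. The whole gene span, also later, left the totals over all lists within 1.5 times and moved single lists, as RUNX2 at T-lineage genes of PER-117 to 24, at immature genes to 11 and 8 and at myeloid genes of KARPAS-45 to 5, and random placement within 100 kb changed only the random means. The causes were not tested, except that shorter lists hold fewer peaks by construction. KARPAS-45-only peaks were less acetylated in the PER-117 than in the KARPAS-45 list except with the strongest lists and at equal covered length by width. At equal length by q the shares were level at 26.9. The strongest H3K27ac regions were also taken by q, which may say little of strength in KARPAS-45. Of the alternative values of main results, 25 stayed within their interval or within 1.5 times and 67 moved, and of the values of single gene lists and domains 192 stayed and 88 moved. A further 10 and 30 rest on the PER-117 H3K27ac list alone, which the equal-length settings leave whole, and could not move. Planned and not run for lack of a genome sequence here were the motif alternatives (stricter peaks, 5000 strongest, windows of 100 bp either side, GC-matched background, a longer consensus) and matching on GC content. Depth was not given, so no limit from depth could be set.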

Other observations

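The tests of the KARPAS-45-only peaks, of weak calls and of a regional level of acetylation were chosen after the result was seen, and those of gaps between regions and of values passed between lines before. Genes in the next paragraph were chosen after their values were seen.

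Genes acetylated at an end in a single line differed in RUNX2. Of 1834 protein-coding genes acetylated in KARPAS-45 only, 43.6% (41.4 to 45.9) carried gene-end RUNX2 in KARPAS-45 and 3.71% in PER-117. Of 725 acetylated in PER-117 only, 12.1% carried it in KARPAS-45 and 29.4% (26.2 to 32.8) in PER-117. These counts used the full lists. Gene-end RUNX2 went with acetylation in general, at 81.4% and 59.1% of genes acetylated in both lines and 4.73% and 1.30% in neither. The contrast therefore restates in large part the overlap of both marks within each line. Among the broad acetylated domains ranked below the first 5, those of KARPAS-45 held MSI2 with 48 RUNX2 peaks, IGF1R with 46, and a cluster on chromosome 19 with DOT1L, the H3K79 methyltransferase of KMT2A leukemia, with 54. Those of PER-117 held NOTCH1 with 12, the repressor GFI1B with 21 and the nuclear receptor RXRA with 17. Inside CDK6, away from its ends, the strongest RUNX2 peak had a fold enrichment of 52.2 in KARPAS-45 and 16.2 in PER-117, and inside CD247 43.1 and 26.3.

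The ratio of KARPAS-45 to PER-117 RUNX2 peaks was 2.04 over all chromosomes and ranged from 1.51 on chromosome 19 to 2.94 on chromosome 18, with 2.89 on chromosome 6 and 2.83 on X. For gene-end peaks it was 1.64 over all chromosomes, and ranged from 1.36 on chromosome 9 to 2.12 on chromosome 21. It was 2.01, 1.83 and 1.81 on 18, 6 and X, of which 6 and X lay below 21, 22, 20, 10 and 8. Across the 23 chromosomes, which are not independent replicates, the gene-end ratio and the ratio of H3K27ac regions had a Spearman rho of 0.561 and a Pearson r of 0.577, and 0.594 and 0.641 without the 2 farthest. Gene density and a shared cause of both ratios had been put to a test on these values. The first was undecided, and the second rested on the Spearman rho of 0.561. The pattern was then set aside in favour of the one on H3K27ac values, so the ratios stand as description only.

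Most KARPAS-45 RUNX2 peaks had no PER-117 partner. Lower sensitivity of the PER-117 list as the whole cause could leave nearly all of the strongest KARPAS-45 peaks shared, and 66.5% of the top 10% were (65.04 to 67.9). This expectation was set after the share was seen. It also takes peaks strong in KARPAS-45 to be strong in PER-117. Over the shared peaks, the fold enrichments of the lines had a Spearman rho of only 0.456. The share therefore does not decide whether lower sensitivity was the cause. Acetylation that also differs between the lines remains a hypothesis: within that top 10%, peaks found in KARPAS-45 only were acetylated in PER-117 at 14.5% (12.8 to 16.4) and shared peaks at 64.4% (62.6 to 66.1), a gap of 49.9 percentage points. In KARPAS-45 the same sets stood at 64.0% and 72.8%. Shared peaks overlap a PER-117 RUNX2 peak by definition, so the gap in PER-117 follows in part from the overlap of both marks there. It therefore cannot decide the hypothesis. A lower sensitivity of the PER-117 list, for all or part of the peaks, and a difference between the 2 libraries rather than the lines, stay open.

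RUNX2 peaks outside H3K27ac were not mainly summits in gaps between acetylated regions, since 17.3% of those in KARPAS-45 (16.7 to 17.9) lay within 500 bp of a region, against 29.8% in PER-117. Weak calls near the threshold as the whole cause would leave few of the strongest peaks outside. Of the top 10% of KARPAS-45 peaks 30.2% were outside (28.8 to 31.5), against 30.4% of the weakest 10%, with 21.98% and 26.2% in PER-117. This expectation was set after the shares were seen, in place of an undecided one, so it is no independent test. The values show only that peaks outside H3K27ac were not confined to weak calls. A part from weak calls stays open: away from gene ends, the median fold enrichment outside H3K27ac was 0.898 of that inside in KARPAS-45 and 0.893 in PER-117, a first test that decided nothing. Distal peaks outside were shared at 19.9% and those inside at 30.7% in KARPAS-45, and at 60.8% and 55.6% in PER-117. No biological explanation was tested.

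In the KARPAS-45 H3K27ac list, consecutive regions had like −log10 q values. A regional level of acetylation would fade with distance, and the Spearman rho between consecutive regions over 300 kb apart was 0.781 (0.761 to 0.8004 over 1567 pairs, across regions that are not independent replicates), which argues against it. Values passed between consecutive lines when the list was made remain a candidate explanation, as the −log10 q of 22351 regions shared with PER-117 had a rho of 0.0669 (0.0534 to 0.0803) with the PER-117 values, while the width of the same regions had 0.335. Width and −log10 q had a rho of 0.0879 in KARPAS-45 and 0.744 in PER-117. No biological explanation was tested. Whether the positions of the KARPAS-45 regions were also affected was not tested either.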
